A study of Mus musculus with 6 samples.

How the data were processed

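The series holds 6 arrays of cultured neonatal mouse ovaries, 3 with 3MC and 3 with vehicle, grouped by the sample titles. Per the labels, total RNA was extracted with guanidinium thiocyanate and phenol, amplified to biotin-labelled cRNA and hybridised to an Illumina Mouse Ref-8 v2 BeadChip. The number of arrays limits the precision. Where the choices below were fixed, they were fixed before the data were examined, except those named as chosen later.

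The authors deposited a table of scanner intensity for 25697 probes, with 1 column per array, no detection p-values and no control probes. These values are not background subtracted, with lowest signals of 72.7 to 80.0 on each array. The authors also deposited a value table of the same probes that was read as log2 values, because each column correlated with log2 of its own array's scanner signal at r = 0.997 or more. Its array medians were 6.62 to 6.63, and how the arrays were normalized is not given in the sources used here. The submitters' processing notes name lumi without a version or role. Further sheets that the authors deposited give, per the file headers, a ratio of 3MC to DMSO, a signed fold change and a p-value for each probe, with the sheet named after an analysis of variance. The p-values are not adjusted, and the model behind them is not given in the sources used here. Set against the spread of these 6 arrays at joined probes, they were smaller than 4 residual degrees of freedom allow at a share of 0.740 of them, so they are printed only as the authors' values. A gene ontology sheet deposited by the authors gives, per the file headers, an enrichment p-value, an enrichment score and the gene numbers of each term. A sheet of 537 rows holds the authors' own selection, with 286 ratios above 1 and 251 below and signed fold changes from -6.09 to 12.16. Of these rows 509 could be joined to a probe, and 509 passed in the same direction in the test used here. That outcome was largely fixed in advance: rows were joined by their ratio on these arrays, and each was 1.5-fold or more.

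The value tables name probes by Illumina identifiers and the comparison sheets name genes by symbol under other identifiers, with no column in common. The ratio of each row was therefore matched to the difference of group means of each probe in the log2 value table. Sorted, both sets of 25697 values differed by at most 8.69e-05 and by 2.55e-06 at the median on the log2 scale. A row was joined to a probe only where each was the other's only partner within 5e-05, which gave 2656 joined rows, and 6 rows had no partner. At a tolerance of 0.0001, 1608 rows were joined, 1602 of them also at the first tolerance. A row joined at both has the same probe by the definition of the join, so this does not check the joins. As a check by a quantity that the join did not use, the spread implied by the authors' p-value correlated with the measured spread of the joined probe across rows at r = 0.549, against 0.007 and 0.041 for the neighbouring probes in order of ratio. Tested on simulated data with the error multiplied by 2, 0.015% of joins were wrong over 20 runs. That error was drawn from the differences between the sorted values, which sorting keeps small. The true share of wrong joins may therefore be higher. Of 540 rows with a fold of 1.5 or more, 512 were joined, but few of those near a ratio of 1. Symbols were updated by accession through a reference table of gene names (assembly GRCm38.p6, used for names only). An accession matched at 23739 of 25697 rows, and 4336 symbols changed, which left 17916 symbols from 18138. Chromosomes are those of the authors' table.

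The scanner intensities were corrected with limma's normexp (offset 50), set to log2 and quantile normalized. The planned correction by negative controls or detection p-values had no values to work on, so its written fallback was used. Probes with a mean signal above that of the median probe were kept (12848). Groups were compared with limma (lmFit and eBayes, two-sided, group as the only term) and Benjamini-Hochberg adjustment over the kept probes, with a threshold of 0.05. Values are means and SD of log2 signal, and log2 fold changes carry limma's standard error. No pair of arrays was identical.

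Gene lists (34, with 11 of markers of ovarian and other cell types) were fixed from textbook knowledge. Each gene was represented by its kept probe of highest mean signal, which gave 2332 genes from 2565 probes. Of 169 symbols with more than 1 passing probe, 9 had passing probes in opposite directions. Lists with at least 5 such genes (24) were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other joined genes, and adjusted over the lists. Camera with an estimated correlation and fry stood beside it. Fry, which asks whether a list's genes move 1 way on balance and compares them with no others, passed 20 lists. The genes named are, in each direction, the 12 of largest log2 fold change among those that passed with groups apart, up to 4 passing members of each list by smallest p, and a set of genes fixed in advance, where joined. That rule gave 129 genes, all past the threshold, some of which are not reported here. Members outside it that are named beside a count of 5 or fewer were chosen after their values were seen.

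The steps were tested on simulated data with the measured means and spread of these arrays. With 200 of 12848 probes changed in this comparison, over 20 runs, 6.00% of those changed by 0.25 on the log2 scale were found, 69.7% of those changed by 0.5 and 99.3% of those changed by 1, and 3.28% of calls were false. A list of 10 genes among 2332 moved by 0.5 was found in 20 of 20 runs, and 5 other lists were called over all runs. In these runs genes varied independently and few others changed, whereas 1993 of the 2332 joined genes passed in the real data. The runs therefore do not give the power of camera on the real lists, and a list that missed may still have moved.

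Alternatives planned before the data were examined were no background correction, median centring, the authors' value table, no filter on dim probes, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each sample in turn, a per-probe analysis of variance, a fold threshold, 1 probe per symbol, the mean of a symbol's probes and camera with an estimated correlation. Chosen after the data were seen were a filter at the 75th percentile of mean signal, cyclic loess, and the ranks of the authors' ratios for all 17916 symbols (cameraPR). A filter on detection p-values and chip as a block were not run, since neither was read from the tables used here. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.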

Results

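Gene expression was measured in ovaries of Swiss mice taken on postnatal day 3 to 4, an age at which the ovary holds mostly primordial follicles, and kept in organ culture for 96 h. The medium held 5 µM 3-methylcholanthrene (3MC), a polycyclic aromatic hydrocarbon that binds the aryl hydrocarbon receptor (AhR), in 3 samples. It held the vehicle, 0.01% dimethyl sulfoxide (DMSO), in 3 others. Each sample was hybridised to an Illumina Mouse Ref-8 v2 BeadChip, which read 25697 probes. The median scanner signal was 109.1, 107.9 and 107.8 in DMSO replicates 1, 2 and 3, and 124.5, 98.1 and 99.4 in 3MC replicates 1, 2 and 3. Across probes, which are not independent replicates, normalized arrays of 1 group correlated at r = 0.995 to 0.996 and arrays of different groups at r = 0.978 to 0.979. The labels do not say whether the 3 samples of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. The moderated test takes that spread mostly from all probes pooled, with 30.8 prior degrees of freedom against 4 of each probe's own. Small p-values therefore do not rest on a gene's own 3 values per group alone.

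The comparison of 3MC with vehicle asks which ovarian transcripts differ after a dose that, per the labels, had been set in pilot work to be overtly toxic. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 11.8-fold with 3MC (log2 fold change 3.56 ± 0.10, SE, n = 3 per group, adjusted p = 5.83e-25). The probe of highest mean signal (ILMN_2634083, chromosome 17), which gave these values, went from a normalized log2 signal of 8.85 ± 0.10 (SD, n = 3) to 12.41 ± 0.28 (SD, n = 3). The other 2 joined probes of Cdkn1a rose by log2 fold changes of 3.37 ± 0.090 and 2.72 ± 0.088. Phlda3, an inhibitor of AKT signalling that p53 induces, rose 6.18-fold (log2 2.63 ± 0.087), and Ephx1, the microsomal epoxide hydrolase that acts on hydrocarbon epoxides, rose 4.86-fold (log2 2.28 ± 0.087). Fpr2, a formyl peptide receptor of myeloid cells, fell by 2.74 ± 0.086 on the log2 scale (6.68-fold lower), and Coro1a, an actin-binding protein of leukocytes, fell by 2.48 ± 0.088 (5.60-fold lower). Genes of the p53 response rose as a group, and genes of macrophages and other leukocytes fell as a group. Immediate early genes passed upward and cholesterol synthesis downward as groups. Neither passed camera with an estimated correlation between genes (adjusted p = 0.236 and adjusted p = 0.400). The estimate was 0.13 for cholesterol synthesis but 0.0142 for immediate early genes, close to the preset 0.01. Their unadjusted camera p still went from 0.000826 to 0.0295. For p53 targets and leukocyte markers the estimates lay below the preset (-0.0091 and -0.0236), yet unadjusted camera p rose to 0.00159 and 0.00116. The immediate early call was therefore not lost through the estimate alone.

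Of 12848 probes kept, 4142 (32.2%) passed an adjusted p of 0.05 in limma's moderated test, with 2029 higher and 2113 lower in 3MC. Over all kept probes, the 3 values of one group lay apart from the 3 of the other at 5450 (42.4%), against 10% by chance. Most shifts were small: the median size of a passing log2 fold change was 0.35, and 689 passing probes changed by 1.5-fold or more (361 higher, 328 lower). A change of 2-fold or more was seen at 103 probes that rose and 96 that fell. The split by direction depended on the scaling, since 49.0% of passing probes were higher in 3MC with quantile normalization and 31.1% (345 higher, 766 lower, of 1111) when each array was only centred on its median. Without 3MC replicate 1, median centring gave 5679 passing probes, 585 higher and 5094 lower.

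**Figure D1:**
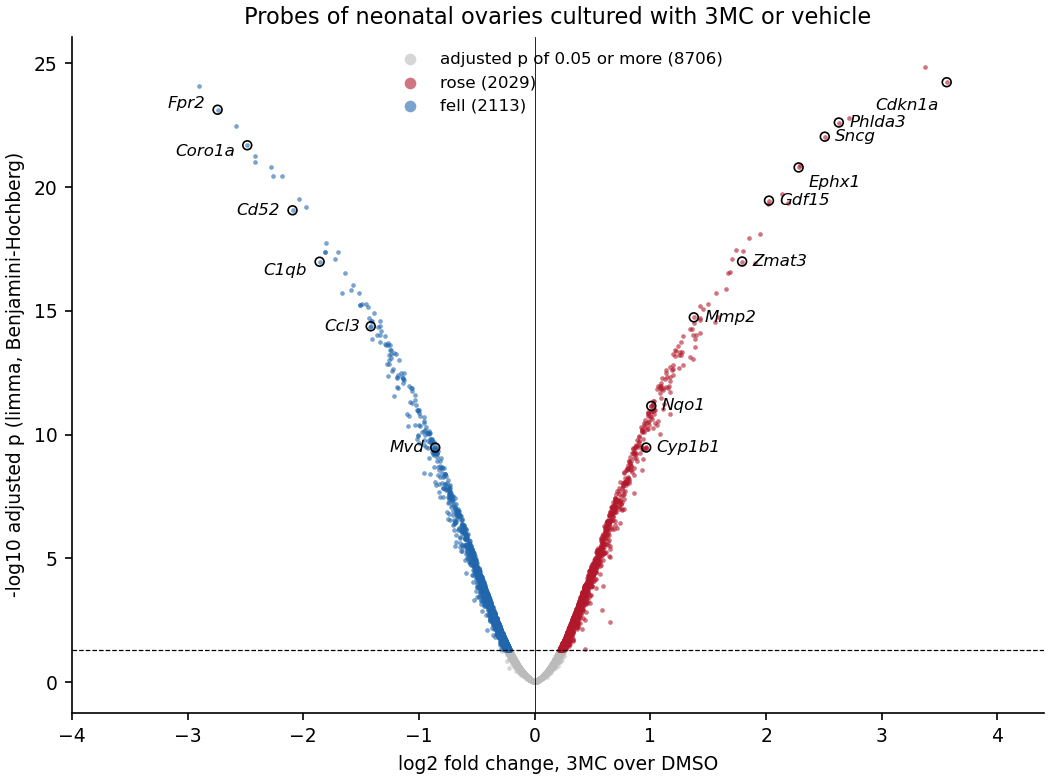
Each point is 1 of the 12848 probes kept, placed by its log2 fold change of 3MC over DMSO and by minus log10 of its adjusted p from limma; the dashed line marks an adjusted p of 0.05. The 2029 probes that rose are red and the 2113 that fell are blue, and Cdkn1a lies at a log2 fold change of 3.56.

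By the naming rule, the other genes of largest rise were Sncg (5.69-fold), Hsd11b1 (4.90-fold), Ak1 (4.57-fold), Gdf15 (4.07-fold), Zfp365 (3.60-fold), Zmat3 (3.46-fold), Ccng1 (3.33-fold), Trp53inp1 (3.22-fold) and Slc25a3 (3.18-fold). Sncg encodes gamma-synuclein, Hsd11b1 the enzyme that regenerates active glucocorticoid, Ak1 an adenylate kinase, and Slc25a3 the mitochondrial phosphate carrier. A second Slc25a3 probe passed in the opposite direction, so that the gene's direction is uncertain. Among the genes of largest fall were LOC100048556 (7.49-fold lower), Fpr2, Abhd16a (5.98-fold lower), Coro1a, Cstdc4 (5.34-fold lower), H2-K1 (4.54-fold lower), Cd52 (4.27-fold lower), H2-T10 (4.11-fold lower), H2-Ab1 (3.93-fold lower), C1qb (3.63-fold lower) and C1qc (3.52-fold lower). H2-K1 and H2-T10 are class I genes of the major histocompatibility complex, whose near-identical relatives can share a probe. H2-Ab1 is a class II gene of antigen-presenting cells, and C1qb and C1qc encode chains of complement C1q, made by macrophages. The standard errors of all 129 genes that the rule named lay between 0.084 and 0.10 on the log2 scale, and each had n = 3 per group. That narrow range comes mostly from the spread pooled over probes and not from each gene's own.

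Genes that p53 induces rose together. Of 21 list members joined to a kept probe, 20 rose and 1 did not pass. All 21 passed when adjusted over the list alone. The member that did not pass over all probes was Tnfrsf10b (log2 0.25), a death receptor. The median log2 fold change of the list was 1.09 (adjusted p = 5.22e-11, limma's camera), and adjusted p = 0.0191 with an estimated correlation. Among its members were Ccng1, an atypical cyclin (log2 1.74 ± 0.086), Zmat3, a zinc finger protein that binds RNA (1.79 ± 0.092), Gdf15, a stress-induced cytokine (2.02 ± 0.086), and Trp53inp1, a nuclear protein that promotes apoptosis (1.69 ± 0.090). In the authors' deposited table, which covers the list whether or not a member was joined, the median log2 ratio of its 30 members was 0.55, and 15 were 1.5-fold or more higher and 0 as much lower. Markers of leukocytes moved with the same contrast and had a median log2 fold change of -1.41.

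Of 15 joined genes of the apoptosis list, 9 rose, 5 fell and 1 did not pass. Adjusted over the list alone, 9 rose and 6 fell. Bbc3, which encodes the BH3-only protein PUMA, rose 2.38-fold (log2 1.25 ± 0.092). The death receptor gene Fas rose 2.13-fold (1.09 ± 0.087), Tnfrsf1a, the receptor for tumour necrosis factor, rose 1.91-fold (0.93 ± 0.086), and Bax, the pore-forming BCL2 relative, rose 1.64-fold (0.72 ± 0.089). Members that fell, named after their values were seen, were Bok (log2 -0.57), Birc5 (-0.48), Casp6 (-0.47), Bik (-0.38) and Casp2 (-0.36). The list as a whole did not pass camera (adjusted p = 0.340). Its members Apaf1, Bax, Bbc3, Fas and Pmaip1, all counted as rises, are also on the p53 list. Of 7 joined DNA repair genes, 1 rose, 4 fell and 2 did not pass. Adjusted over the list alone, 1 rose and 6 fell (list adjusted p = 0.484). Ercc5, an excision repair endonuclease, rose 1.78-fold (log2 0.83 ± 0.090), while Brca2, of homologous recombination, fell by 0.63 ± 0.088. Of 10 joined cell cycle genes, 5 rose and 5 fell, over all probes and adjusted over the list alone (list adjusted p = 0.856). Ccnd2, a D-type cyclin of granulosa cells among others, rose 2.24-fold (1.17 ± 0.094), and Birc5 and the replication licensing factor Cdt1 fell, by 0.48 ± 0.087 and 0.44 ± 0.084.

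**Figure D2:**
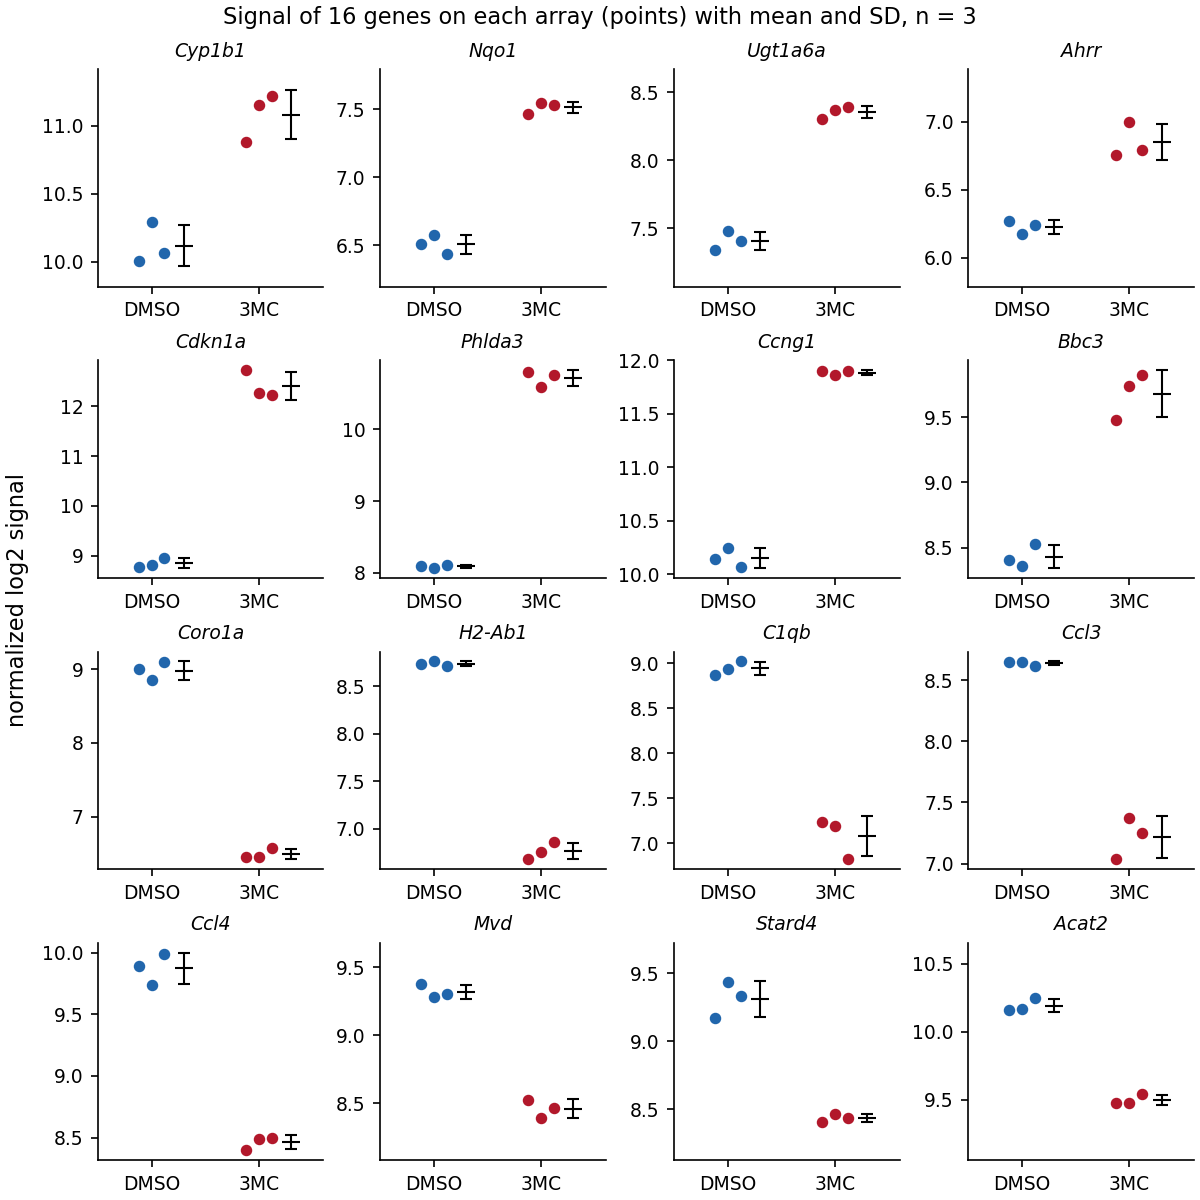
Points are the normalized log2 signal of 16 genes on each of the 6 arrays, with the mean and SD of each group (n = 3) beside them; axis ranges differ between genes. The 3 values of each group lie apart in every panel, with 3MC above DMSO in the upper 8 panels (AhR and p53 target genes) and below it in the lower 8 (leukocyte, chemokine and cholesterol genes).

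Known targets of the AhR that could be joined to a probe all rose. Nqo1, a quinone reductase, rose 2.01-fold at its joined probe (log2 1.01 ± 0.085), while another row of Nqo1 in the authors' deposited table, not joined, had a ratio of 1.048 (p = 0.0476). Cyp1b1, a cytochrome P450 that oxidises polycyclic hydrocarbons, rose 1.95-fold (0.96 ± 0.096) from a log2 signal of 10.12 ± 0.15 (SD, n = 3) to 11.08 ± 0.18 (SD, n = 3). The glucuronosyltransferase gene Ugt1a6a rose 1.93-fold (0.95 ± 0.085), and Ahrr, the AhR repressor, rose 1.54-fold (0.62 ± 0.088). These were 4 of the list's members, and the same 4 passed when adjusted over the list alone. With fewer than 5 joined genes the list was not tested with camera. In the authors' deposited table, 16 members had a median log2 ratio of 0.06, 3 were 1.5-fold or more higher, and ranks over all symbols placed the list higher (adjusted p = 0.0389, cameraPR, chosen after the data were seen). The ratio of 3MC to DMSO in the authors' deposited table was 0.993 for Cyp1a1 (p = 0.831), 1.033 for Tiparp (p = 0.381) and 0.944 for Ahr (p = 0.00561), and 1.023 and 1.000 at 2 rows of Cyp1a2, with unadjusted p-values of the authors' model. None of these 4 genes could be joined to a probe, so it is unknown whether their probes had signal above background. Ratios near 1 therefore do not show that these genes were unchanged. Of the 2 joined genes of the AhR complex, 1 rose and 1 fell, over all probes and adjusted over the list alone. Neither passed with median centring (Ptges3 0.33, adjusted p = 0.246, and Hsp90ab1 -0.53, adjusted p = 0.131), and Hsp90ab1 did not pass without 3MC replicate 3 (-0.28, adjusted p = 0.0573).

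Genes of the NRF2 and glutathione list went both ways, with 4 rises, 4 falls and 1 that did not pass among 9, and the same counts adjusted over the list alone. Its median log2 fold change was -0.17 while its mean was 0.21 and camera's direction was up (adjusted p = 0.822), with a median log2 ratio of -0.025 over 29 members in the authors' deposited table. Ephx1, Nqo1 and the NADPH-producing malic enzyme Me1 (log2 0.74 ± 0.091) rose, and the microsomal glutathione transferase Mgst1 fell by 0.97 ± 0.091. Of 4 joined antioxidant enzymes, 2 rose and 2 fell, also adjusted over the list alone. Gpx3, a secreted glutathione peroxidase, rose 2.21-fold (1.14 ± 0.087), Sod3, the extracellular superoxide dismutase, rose 1.58-fold (0.66 ± 0.090), and Gpx4, which reduces lipid peroxides, fell by 0.45 ± 0.087.

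Markers of macrophages and other leukocytes fell without exception among those joined. All 19 joined members fell, also adjusted over the list alone, with a median log2 fold change of -1.41 (adjusted p = 8.54e-13, camera) and adjusted p = 0.0191 with an estimated correlation. Coro1a, Cd52 (a surface glycoprotein of leukocytes), H2-Ab1 and Laptm5, a lysosomal protein of blood cells (fell by 1.70 ± 0.085), had the smallest p-values. In the authors' deposited table, 20 of 26 members were 1.5-fold or more lower and 0 as much higher, with a median log2 ratio of -0.88. Another 6 members, none joined to a probe, lay within 0.2 of a log2 ratio of 0 in the authors' deposited table. They were Ptprc (0.05, mean of its rows), Fcer1g (0.04), Itgam (0.03), H2-Aa (0.06), Ctss (-0.07) and Cd3e (-0.03), and the signal of their probes is unknown. The authors' deposited gene ontology sheet listed immune response first, with 34 of its 296 genes on their list (enrichment p = 4.51e-12), followed by chemokine activity (10 of 31, p = 8.42e-09). Their list came from these same arrays and held 286 ratios above 1 and 251 below, so the terms give no direction.

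Inflammatory genes divided. Of 11 joined members 6 rose and 5 fell, also adjusted over the list alone, the median log2 fold change was 0.29 and the mean -0.12, and camera's direction was down (adjusted p = 0.896). The median log2 ratio of 26 members in the authors' deposited table was 0.02. The chemokines Ccl3 and Ccl4, made by macrophages among other cells, fell by 1.42 ± 0.090 and 1.41 ± 0.088, and Tnf fell by 0.83 ± 0.092. Cxcl1, a neutrophil attractant, rose 1.75-fold (0.81 ± 0.086). Of 9 joined interferon response genes 8 rose and 1 fell, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.108). Usp18, which trims the ubiquitin-like ISG15 from proteins, rose 1.64-fold (0.72 ± 0.088), and Psmb9, an immunoproteasome subunit, fell by 1.02 ± 0.097. Beside both lists, the leukocyte markers had a median log2 fold change of -1.41.

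Cholesterol synthesis fell as a group: 12 of 13 joined genes fell and 1 did not pass, also adjusted over the list alone. The median log2 fold change was -0.54 (adjusted p = 0.00433, camera), a call lost at adjusted p = 0.400 with an estimated correlation. Stard4, a carrier of cholesterol between membranes, fell by 0.88 ± 0.088, and the enzyme genes Mvd and Acat2 fell by 0.86 ± 0.085 and 0.69 ± 0.084. The member that did not pass was Insig1 (log2 0.19). In the authors' deposited table, 6 of 21 members were 1.5-fold or more lower, and the list's median log2 ratio was -0.43. All 6 joined immediate early and heat shock genes rose, also adjusted over the list alone, with a median of 0.84 (adjusted p = 0.00496, camera), a call lost at adjusted p = 0.236 with an estimated correlation. Fos, a subunit of the AP-1 transcription factor, rose 2.62-fold (1.39 ± 0.092), Egr1, a zinc finger transcription factor, 1.86-fold (0.90 ± 0.088), Ier3 1.80-fold (0.85 ± 0.085) and Junb 1.79-fold (0.84 ± 0.085). In the authors' deposited table, 5 of 24 members were 1.5-fold or more higher and 0 as much lower, and the list's median log2 ratio was 0.21. With median centring, 4 of the 6 joined immediate early and heat shock genes passed, and 9 of the 13 of cholesterol synthesis. Beside both lists, the leukocyte markers had a median log2 fold change of -1.41. Of 7 joined genes of endoplasmic reticulum stress 5 rose and 2 did not pass, also adjusted over the list alone (list adjusted p = 0.330). Calr, a chaperone that binds calcium, had a log2 fold change of 0.65 ± 0.10, and with median centring 0.51 (adjusted p = 0.0667). Trib3, Edem1 and Dnajb9, also counted as rises, lost the call with median centring too (limma adjusted p = 0.1675, 0.2856 and 0.7765).

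**Figure D3:**
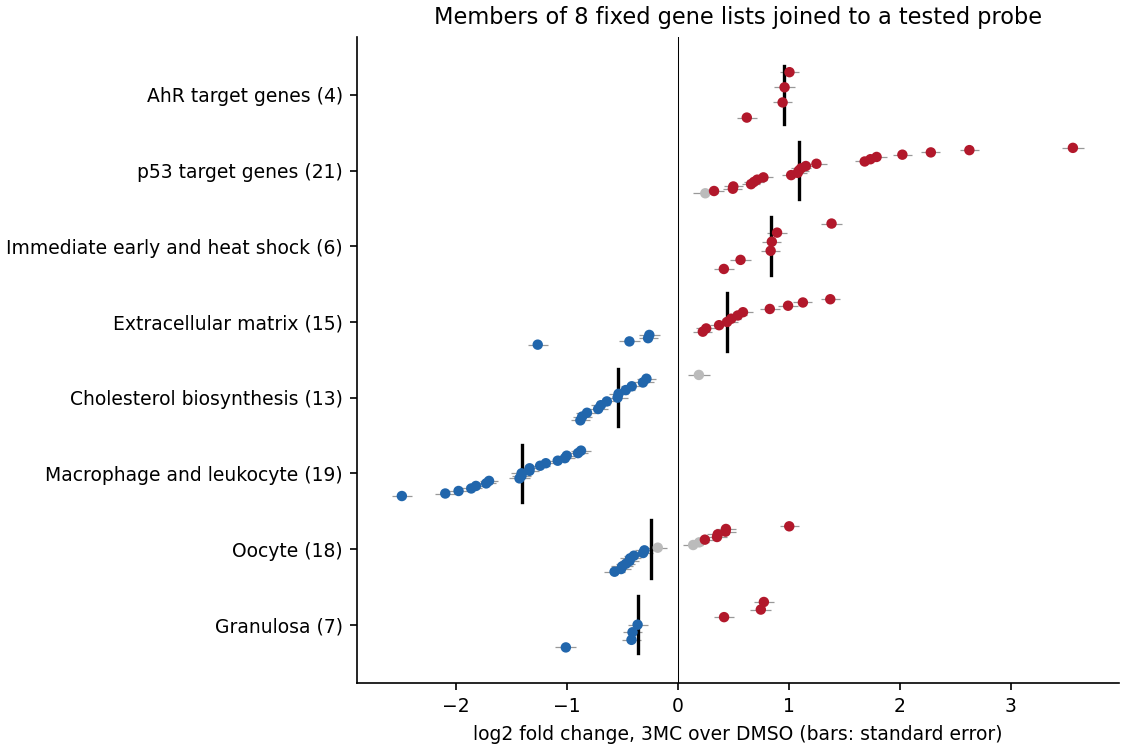
Points are the log2 fold changes of 3MC over DMSO of the members of 8 gene lists that were joined to a kept probe (number in brackets), with standard errors; red rose, blue fell and grey did not pass, and the black bar is the list's median. The 19 leukocyte markers all lie below 0, around a median of -1.41, and the 21 p53 targets all lie above 0, around 1.09.

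Oocyte genes moved in both directions. Of 18 joined members 6 rose, 9 fell and 3 did not pass, and adjusted over the list alone 7 rose and 10 fell. The median of the joined members was -0.24 (adjusted p = 0.822, camera), and the median log2 ratio of 39 members in the authors' deposited table was -0.09. Oosp1, a secreted protein of oocytes, rose 2.01-fold (1.01 ± 0.087). Members that fell included the transcription factor genes Pou5f1, by 0.51 ± 0.091, Figla, required to form primordial follicles, by 0.50 ± 0.096, and Sohlh1, by 0.47 ± 0.085. Oas1c, an oligoadenylate synthetase of the ovary, fell by 0.57 ± 0.095. Bmp15, a growth factor of growing oocytes, had a log2 fold change of 0.44 ± 0.090 (adjusted p = 0.00027), and with median centring 0.31 (adjusted p = 0.262). Gdf9, another such factor, passed narrowly (log2 0.25 ± 0.088, adjusted p = 0.0303). It lost the call with median centring (0.02, adjusted p = 0.968), with cyclic loess (0.20, adjusted p = 0.0777), and without DMSO replicate 1 (0.23, adjusted p = 0.0839), DMSO replicate 3 (0.23, adjusted p = 0.100), 3MC replicate 1 (0.24, adjusted p = 0.0612) or 3MC replicate 2 (0.18, adjusted p = 0.162). Of 3 joined genes of meiotic prophase, Smc1b and Stag3, cohesin subunits of meiosis, fell, by 0.75 ± 0.090 and 0.46 ± 0.092, and the meiotic cohesin gene Rec8 had a log2 fold change of 0.31 ± 0.087 (adjusted p = 0.00535), and with median centring 0.26 (adjusted p = 0.367). The same 1 rise and 2 falls were counted adjusted over the list alone.

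For the signalling through phosphoinositide 3-kinase (PI3K) and AKT that sets primordial follicles growing, too few of the list's members were joined for a test with camera. Tsc2, an inhibitor of the mTORC1 kinase, had a log2 fold change of -0.28 ± 0.087 (adjusted p = 0.0117), also past the threshold adjusted over the list alone. It did not pass with median centring (-0.40, adjusted p = 0.137) or without DMSO replicate 2 (-0.23, adjusted p = 0.0747). In the authors' deposited table the list's 33 members had a median log2 ratio of -0.03, and 0 were 1.5-fold or more higher or lower. The ratios in the authors' deposited table were 1.036 for Foxo3 (p = 0.491), 0.979 for Akt1 (p = 0.563), 1.069 for Amh (p = 0.319), and 1.006 and 1.015 at 2 rows of Kitl (p = 0.868 and 0.520). These rows were not joined to a probe either, so whether they had signal above background is unknown. Kit was not analysed here.

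Markers of somatic ovarian cells gave mixed counts. Of 7 joined granulosa genes 3 rose and 4 fell, also adjusted over the list alone, with a median of -0.36 (adjusted p = 0.899), while the median log2 ratio of 24 members in the authors' deposited table was 0.05. The bile acid receptor gene Nr1h4 rose 1.71-fold (0.78 ± 0.088), Cyp19a1, which encodes aromatase, rose 1.68-fold (0.75 ± 0.094), and Lgr5, a receptor for R-spondins, fell by 1.01 ± 0.095. Of 7 joined genes of the surface epithelium 4 rose and 3 fell, also adjusted over the list alone. That list's median was 0.34 and its mean -0.01, and camera's direction was up (adjusted p = 0.936), while the median log2 ratio of 14 members in the authors' deposited table was -0.03. Upk1b, a uroplakin, rose 2.61-fold (1.38 ± 0.095), while Lgals2, a galectin, fell by 1.43 ± 0.089 and the keratin gene Krt19 by 0.62 ± 0.096. Of 9 joined markers of theca and stroma 6 rose and 3 fell (adjusted p = 0.330), and of 7 of smooth muscle and pericytes 6 rose and 1 fell (adjusted p = 0.251), with the same counts adjusted over each list alone. Thy1, a surface protein of fibroblasts, rose 1.69-fold (0.76 ± 0.087), and Smtn, of contractile smooth muscle, rose 1.63-fold (0.70 ± 0.087). All 3 joined endothelial markers fell, also adjusted over the list alone: Ptprb by 0.50 ± 0.088, Esam by 0.41 ± 0.094 and Cldn5 by 0.29 ± 0.090. Over all 21 members of the endothelial list in the authors' deposited table, the median log2 ratio was -0.0038 and 0 were 1.5-fold or more higher or lower. Cldn5 lost the call with median centring (-0.32, adjusted p = 0.221), without DMSO replicate 3 (-0.25, adjusted p = 0.0638) and without 3MC replicate 2 (-0.21, adjusted p = 0.107).

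Of 24 lists tested with camera, 4 passed, and 2 of these, the p53 targets and the leukocyte markers, passed with an estimated correlation as well. Joined genes are mostly those whose ratio stands alone, hence mostly changed ones, so counts among joined members are not shares of a whole list. For the same reason, passing when adjusted over a list alone adds no separate support for any list.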

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

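The filter at the 75th percentile, cyclic loess and the ranks of the authors' ratios were chosen after the data were seen. Of the settings that kept all samples, median centring gave 1111 probes past the threshold against 4142, and 1110 of these passed in the same direction with quantile normalization. The stricter filter left 2535 of 6424 probes (fewer tested), a per-probe analysis of variance with adjustment 1850 (no spread shared between probes), a fold of 1.5 or more 689 and 1 probe per symbol 2171 (fewer tested). Without adjustment the analysis of variance gave 4305. The other settings gave 3990 (replicate block) to 4185. Leaving out each sample gave 3361 to 3608 probes, 4 lists each time and 123 to 126 of the 129 named genes. Lists past the threshold numbered 2 with an estimated correlation, which loses cholesterol synthesis and immediate early genes, 11 of 34 by ranks of the authors' ratios (the cause was not tested, since genes, values and statistic all differ), and 4 in all other settings. Named genes past the threshold numbered 96 with median centring and 127 to 129 in the other settings with all samples and the same filter, and neither a named gene nor any of the 4 lists that passed turned its direction. By ranks, 5 lists that passed in neither test went the other way: down for NRF2 with glutathione, autophagy with lysosome, and surface epithelium, up for inflammation and granulosa. The replicate block changed no named gene or list. Same-numbered samples deviated with r = -0.08, -0.10 and 0.08, and 2 of 6 samples correlated best with their own number. Normexp without detection p-values, planned as an alternative, became the setting reported. Other splits of the 6 samples gave at most 0 probes against 4142 and at most 5 lists against 4. The real split included, 1 of 10 splits gave as many probes and 6 of 10 as many lists, too few splits for a share under 0.05. Each other split also mixed treated and vehicle samples in both of its groups. Any treatment difference then added to the spread within groups, which lowers the probe count, while part of it stayed between the groups. These splits therefore do not show what counts arise without an effect, and no conclusion is drawn from them. Signal over background cannot be given without detection p-values, so changes of dim probes are understated by an unknown amount.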

Other observations

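The tests on leukocyte markers and on p53 targets were chosen after those results were seen, as were the ranks of the authors' ratios and cyclic loess. Extracellular matrix genes mostly rose: of 15 joined members 11 rose and 4 fell, also adjusted over the list alone. Mmp2, a gelatinase of stromal cells, rose 2.59-fold (log2 1.38 ± 0.085, n = 3 per group), Lox, which cross-links collagen, rose 2.19-fold (1.13 ± 0.087), and Col3a1, a fibrillar collagen, rose 1.99-fold (1.00 ± 0.087). Mmp9, the gelatinase of neutrophils and macrophages, fell by 1.26 ± 0.091 beside the leukocyte markers. The list missed the threshold in camera (adjusted p = 0.108), while by ranks of all ratios in the authors' deposited table it passed upward (adjusted p = 6.83e-05). The same ranks passed upward for interferon response (adjusted p = 1.89e-05), theca and stroma (0.00191), endoplasmic reticulum stress (0.00406) and hypoxia and glycolysis (0.0442), and downward for ribosomal proteins (0.00191). Camera gave adjusted p = 0.330 for hypoxia and glycolysis, where of 10 joined genes 7 rose, 2 fell and 1 did not pass (7 and 3 adjusted over the list alone). Egln3, an oxygen-sensing hydroxylase, rose 1.83-fold (0.88 ± 0.091) and Vegfa, the endothelial growth factor, 1.51-fold (0.60 ± 0.088), but Aldoc, an aldolase, fell by 0.95 ± 0.086.

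Of 9 joined Wnt and Notch genes 6 rose, 2 fell and 1 did not pass, also adjusted over the list alone (camera adjusted p = 0.330). Wnt5a, a ligand of the stroma, rose 2.12-fold (log2 1.09 ± 0.10), and the receptor genes Notch3 and Fzd1 rose 1.81-fold and 1.62-fold. Of 12 joined genes of TGF-beta and BMP signalling 8 rose, 3 fell and 1 did not pass, and adjusted over the list alone 9 rose and 3 fell (adjusted p = 0.330). Its receptor gene Tgfbr1 had a log2 fold change of 0.59 ± 0.086, and with median centring 0.44 (adjusted p = 0.0879). Tgfbr2, Bmp15 and Acvr1, also counted as rises, lost the call with median centring too (limma adjusted p = 0.1931, 0.2618 and 0.2791). Of 5 joined ribosomal protein genes 1 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.330), with Rpl22 falling by 0.52 ± 0.087. Oxidative phosphorylation had 2 rises, 3 falls and 2 genes that did not pass (2 and 4 adjusted over the list alone, adjusted p = 0.856), and Sdhc, a subunit of succinate dehydrogenase, fell by 0.41 ± 0.086. Autophagy and lysosome had 2 rises, 1 fall and 2 that did not pass (4 and 1 adjusted over the list alone, adjusted p = 0.575), and Atg3 rose 1.71-fold. Of retinoid genes 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.780), with the retinaldehyde dehydrogenases Aldh1a1 rising 1.71-fold and Aldh1a2 falling by 0.55 ± 0.086. Too few genes were joined to test steroidogenic markers (1 rose), oviduct markers (1 fell, Wfdc2, by 0.70 ± 0.095), adipocyte markers (1 rose, 1 fell) or erythroid markers (0 joined), with the same counts adjusted over each list alone. Median log2 ratios of these lists in the authors' deposited table were -0.0041, 0.05, -0.02 and -0.0020, in that order. The steroidogenic gene that rose, Fdxr, lost the call with median centring (log2 0.12, limma adjusted p = 0.738). It also lost it without DMSO replicate 1, DMSO replicate 3, 3MC replicate 1 or 3MC replicate 3. The adipocyte gene that rose, Lpl, lost the call with median centring (log2 0.39, limma adjusted p = 0.0913).

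Leukocyte markers, 1 of whose 27 genes is also on another list, fell together, with a median log2 fold change of -1.41. The probes of Lyz1 and Lyz2, lysozymes of myeloid cells, went from normalized log2 signals of 13.79 and 12.81 to 12.39 and 11.09. Over the 4 other normalizations the median came no nearer 0 than -1.18, so the fall of joined members did not hinge on that choice. Normalization of the arrays is not excluded by this. The members were joined by their ratio in 1 of these 4, the authors' values, which favours large ratios. Fewer leukocytes in the 3MC cultures may account for the fall, but 6 list members lay within 0.2 of a log2 ratio of 0 in the authors' deposited table, and without a joined probe it is unknown whether these had signal to lose. Lower expression in leukocytes that were still present, an action of 3MC on those cells, was not tested and stays open too.

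The p53 targets rose together. The lowest median over the 4 other normalizations was 0.93, so the rise of joined members did not hinge on that choice. These members too were joined by their ratio in the authors' values, 1 of the 4. A fall of the median towards 0 was therefore unlikely from the start, and normalization is not excluded. A lower share of leukocytes, which raises all other transcripts alike, is argued against as the whole cause: the highest median log2 ratio of the other marker lists in the authors' deposited table was 0.14 (theca and stroma), below the lower 95% bootstrap bound of 0.31 on the p53 list's median of 0.55 (30 members, 10000 draws). That bound takes the genes of the list as independent and is not a spread over samples. The marker medians include members of unknown signal, which pull them towards 0 if they had none. Among joined members, all with signal above the median probe, the highest median of the other marker lists was 0.41 (smooth muscle and pericyte), against 1.09 for the p53 targets. Joined members are mostly changed ones in both. A p53 response to 3MC in ovarian cells remains a candidate explanation, as a hypothesis found and tested on the same data.

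Median centring gave fewer probes past the threshold, as set out with the processing. Cyclic loess, which removes differences between arrays along the signal level, gave 4109 probes, which is consistent with such differences behind the lower count. Brightness of 3MC replicate 1 stays open: without that array median centring gave 5679 probes (585 higher, 5094 lower) against 3608 with quantile normalization, and without each other array 517 to 1215. The first count overshoots what the test had asked for, so neither outcome written for it was met. No biological explanation was tested for this pattern.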
